A study of Homo sapiens with 2 samples.

How the data were processed

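RNA of H6c7, an immortalised line of human pancreatic duct epithelium, and of H6c7 cells into which a K-ras oncogene had been introduced was measured on Affymetrix U133A arrays, with 1 array per line. Per the labels, RNA was isolated with phenol and chloroform, cleaned on silica columns and converted to cRNA by the manufacturer's protocol. The labels do not say whether the K-ras cells were a pool or a clone, and they name no vector control.

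The deposited table holds 1 intensity per probe set and array, on a linear scale, for 22283 probe sets, of which 68 are controls. The software that made these intensities is not given in the sources used here. The mean over probe sets after leaving out the lowest and highest 2% was 150.06 in both columns as deposited, the form of a signal that the authors' software had scaled to a common target, so the table was taken as already scaled. Detection calls and probe-level data were not used here.

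Genes were named through the array's annotation. It pairs 19071 probe sets with exactly 1 gene symbol and 1043 with several, and 2169 probe sets are unnamed here. Of the 19071, 19059 were matched by gene number to the symbols of GRCh38.p14, and no symbol needed updating. Probe sets with several names were left out of the gene table. Genomic spans, chromosomes and the order of genes were taken from the same GRCh38.p14 reference, and positions of single genes are not given. XIST and Y-linked genes were left out.

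The 2 columns were rescaled to the same trimmed mean, which changed values by a negligible amount. Of several probe sets of a gene, the one with the highest mean log2 signal over both arrays was used. The floor was the higher of the 2 arrays' medians over non-control probe sets, a signal of 46.9, which lies above the highest bacterial control signal of 36.3. A gene below the floor on both arrays was called not measured. A gene below it on 1 array has a ratio that is a bound against the floor, written as at least N-fold. A gene was counted as higher or lower in the K-ras line when its ratio was at least 2-fold. With 1 array per group there is no spread between samples, no p-value and no standard error, and the number of arrays limits the precision of every value.

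The one repeat measurement within the data is that between probe sets of the same gene. It is technical. Over 1671 genes with 2 or more probe sets above the floor on both arrays, the pooled standard deviation of the log2 ratio between probe sets of 1 gene was 0.46, against 0.92 between genes.

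A total of 32 gene lists cover pathways, cell type markers and complexes. These lists, the rule for naming genes and the 11 alternative settings given here were fixed before the data were examined. For each list with at least 5 measured members, the median log2 ratio was ranked among the medians of 10000 random lists of the same size matched on mean log2 signal in 10 bins. A list was said to stand apart with a percentile under 2.5 or over 97.5. This percentile describes these 2 arrays and is no test of the oncogene. Another 10 lists were chosen after the table of genes had been seen and appear only among the additional observations.

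Named genes are the 15 highest and 15 lowest ratios among genes above the floor on both arrays, with a higher signal of at least 2 times the floor and no other probe set above the floor on both arrays going the other way. To these come the 5 largest bounds in each direction, up to 4 members of each list with the largest ratios, and HRAS. Further list members, chosen after their values were seen, are named to show what a count consists of. Probe sets whose name ends in _x_at can pick up related transcripts, and genes measured by them are called uncertain.

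The alternative settings were the values as deposited, quantile normalization, median centring, a loess curve with a span of 0.3, scaling on the 100 probe sets numbered 200000 to 200099, floors at the 30th and 70th percentile, no floor, the floor as a pseudocount, the median over probe sets, and leaving out _x_at and _s_at probe sets. A threshold of 3-fold was tried for the counts. One alternative was added after the data were seen. It removed the relation of the log2 ratio to the genomic span of the gene and to the median of the 20 nearest measured genes.

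The procedure was tested on simulated arrays made from the parental signals with the spread between probe sets as noise. The changed genes were drawn from those with a parental signal well above the floor. At the 2-fold threshold, 90 of 100 genes changed 3-fold and 100 of 100 genes changed 6-fold were recovered, and 165 of 6958 unchanged genes were called. A list shifted 2-fold stood apart, as did 1 of 26 unshifted lists. The simulation held no differences between cultures, RNA samples or labelling, so these shares are not error rates of the real comparison. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.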

Results

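Transcript levels were measured in H6c7, a near-normal human pancreatic duct epithelial line immortalised with papillomavirus genes, and in H6c7 cells carrying a K-ras oncogene. The comparison asks which transcripts differ once the oncogene is present. Each line is represented by 1 array, so the values below have no replicate error and no difference could be tested. The median signal was 43.9 on the parental array and 46.9 on the K-ras array. Apart from the controls, 10791 probe sets were at or above the floor of 46.9 on the parental array and 11109 on the K-ras array. Across all probe sets the log2 signals of the arrays correlated with Pearson's r = 0.88, a value over probe sets, which are not independent replicates. Hybridisation spikes, added in equal amounts to check the staining, differed between arrays by log2 ratios of -0.31 to 0.29 over 18 probe sets.

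The K-ras line had higher levels of many transcripts of the amino acid and unfolded protein stress response and of RAS-MAPK output, and lower levels of many transcripts for DNA replication, mitosis and heat shock proteins. Of 7690 measured genes, 767 (9.97%) were at least 2-fold higher and 1108 (14.4%) at least 2-fold lower in the K-ras line. Among the 5995 genes above the floor on both arrays, 665 were higher and 806 lower. The others were bounds, 102 higher and 302 lower. Scaling on 100 maintenance probe sets raised the median log2 ratio of genes above the floor on both arrays by 0.16. It turned the balance, to 1093 genes higher and 843 lower. With no floor the balance turned too, to 2419 higher and 1796 lower. In the scaling used throughout, the median log2 ratio of genes above the floor on both arrays was 0.10.

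**Figure D1:**
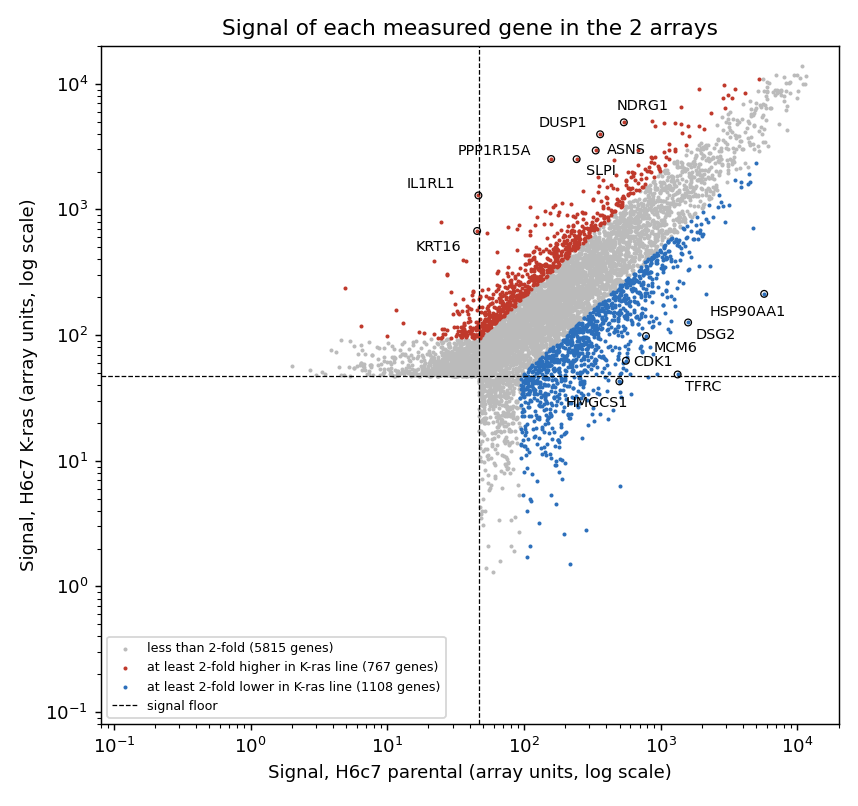
Signal of each measured gene on the parental array (x axis) and the K-ras array (y axis), both in array units on log scales, with 1 point per gene and dashed lines at the floor of 46.9. The 767 genes at least 2-fold higher in the K-ras line lie at the upper left and the 1108 at least 2-fold lower at the lower right.

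The highest ratio among genes above the floor on both arrays was that of PPP1R15A, which encodes a phosphatase subunit that restores translation after stress. Its signal was 158 in the parental line and 2519 in the K-ras line, a 15.9-fold difference, and its other probe set gave a log2 ratio of 4.39 against 3.99. The elastase inhibitor PI3 was 12.2-fold higher, and the secreted protease inhibitor SLPI 10.4-fold. The signal of the MAP kinase phosphatase DUSP1 was 361 in the parental line and 3961 in the K-ras line. The glutathione-degrading enzyme CHAC1 was 9.42-fold higher, asparagine synthetase ASNS 8.80-fold, the transcription factor ATF3 6.94-fold and PHGDH, the first enzyme of serine synthesis, 6.47-fold. GADD45B, a stress-inducible gene, was 9.52-fold higher, with log2 ratios of 2.30 and 3.25 in its 2 probe sets above the floor. The mitochondrial carboxykinase PCK2 had a log2 ratio of 3.04. NDRG1 was 9.17-fold higher, the secreted glycoprotein STC2 7.86-fold, GTPBP2 6.78-fold and the cornified envelope precursor SPRR1B 6.52-fold. EPS8L1 was 7.24-fold higher in an uncertain _x_at probe set, but its other 3 probe sets above the floor gave log2 ratios of only 0.96 to 1.16.

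Some transcripts were below the floor in the parental line and well above it in the K-ras line. IL1RL1, a receptor of the interleukin-1 family, was at least 27.5-fold higher, with a signal of 1292 in the K-ras line. The keratin KRT16, typical of activated squamous epithelium, was at least 14.4-fold higher, the calcium-binding protein S100P at least 8.47-fold and the sterol transporter ABCG1 at least 8.33-fold. SPRR2B was at least 16.9-fold higher but rests on an uncertain _x_at probe set.

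The lowest ratios in the K-ras line were those of the transferrin receptor TFRC and of HSP90AA1, the inducible cytosolic HSP90. TFRC had a signal of 1331 in the parental line and 48.6 in the K-ras line, a 27.4-fold difference. HSP90AA1 was 26.9-fold lower, from 5717 to 213, and its 4 probe sets gave log2 ratios of -5.56 to -4.75. BCLAF1 was 19.2-fold lower, and other probe sets gave bounds at log2 ratios of -2.02 and -0.73. The desmosomal cadherin DSG2 was 12.6-fold lower, and the actin-regulatory genes NCKAP1 and ARHGAP29 were 12.5-fold and 11.1-fold lower. DST, which encodes a cytoskeletal linker, was 10.7-fold lower. Genes of RNA handling and translation were U2SURP (12.1-fold lower), MTIF2 (10.3-fold), EIF3E (10.2-fold), LRPPRC (9.96-fold) and DDX1 (9.87-fold). COMMD8, the deubiquitinase USP1 and the chromatin protein DEK were 10.4-fold, 10.3-fold and 10.2-fold lower. The K-ras signals of TFRC, MTIF2, BCLAF1, U2SURP, USP1 and DST were 48.6 to 52.3, just above the floor. Their ratios are thus close to bounds. Below the floor in the K-ras line alone were RDX, a membrane-actin linker, at least 17.2-fold lower, COPS2 at least 12.8-fold, ASCC3 and METAP2 each at least 10.8-fold, and KTN1 at least 10.9-fold on an uncertain probe set. A second RDX probe set, above the floor on both arrays, gave a log2 ratio of -1.93.

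Genes with several probe sets showed how far single values can be relied on. Of 167 genes at least 2-fold higher with another probe set above the floor on both arrays, all other probe sets had the same sign in 159 (95.2%) and passed 2-fold in 90 (53.9%). Of 231 genes at least 2-fold lower, the same held for 197 (85.3%) and 113 (48.9%).

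Of 29 gene lists with enough measured members, 8 stood apart as higher in the K-ras line and 4 as lower. Lists of randomly drawn genes would put 1.45 of 29 outside the limits. Genes of a list may vary together and some lists share members, so 1.45 is no measure of chance here. The unfolded protein and amino acid stress list stood furthest to the higher side, with a median log2 ratio of 1.27 over 20 measured members, above all of 10000 matched random lists. In it 11 genes were at least 2-fold higher and 1 lower. Beside CHAC1, ASNS, ATF3 and PHGDH these included TRIB3 (log2 ratio 2.25), CEBPB (2.20), ATF4 itself (1.94) and PSAT1 (1.85), with XBP1, DNAJB9 and HERPUD1 at 1.37, 1.56 and 1.17. Other members of the list, which serve protein folding in the endoplasmic reticulum, had smaller or negative ratios. HSPA5 had a log2 ratio of 0.63, CALR 0.55 on an uncertain probe set with another at 1.59, PDIA4 -0.02 and HSP90B1 -1.74, also uncertain and the one member at least 2-fold lower. The list stood above all matched random lists under each of the 11 alternative settings.

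A list of genes known to respond to RAS and MAP kinase signalling was also higher as a group, though what drove their levels was not tested. The RAS-MAPK output list had a median log2 ratio of 0.90 over 25 measured members, above all matched random lists, with 12 at least 2-fold higher and 1 lower. DUSP1 and DUSP5 (5.85-fold higher), which switch MAP kinases off, led the list, followed by the transcription factors MAFF (3.89-fold) and JUNB (3.18-fold). SPRY4, ETV4, ETV5, FOSL1, PHLDA1, IER2, IER3 and EPHA2 had log2 ratios between 1.13 and 1.53, though other probe sets of PHLDA1 gave values from -0.13 to 3.10. The ERK-specific phosphatase DUSP6 had a log2 ratio of 0.56, CCND1 0.06, FOS 0.07 and EGR1 -0.48, all under 2-fold. Also under 2-fold were DUSP4 (0.42), SPRY1 (0.34), SPRY2 (0.90) and SPRED2 (0.33). ELK3 was lower at -1.54, with another probe set at 0.74. In the list of EGF family ligands and receptors (median log2 ratio 0.73, percentile 98.6, 9 measured) 3 members were at least 2-fold higher and 1 lower. The ligand HBEGF was 5.47-fold higher and the receptor EGFR 3.75-fold, both with a second probe set giving more than 2-fold. NRG1 was 3.36-fold higher, with other probe sets at log2 ratios down to 0.20. The receptor MET was 3.23-fold lower, but its other probe sets gave log2 ratios of only -0.73 to -0.68. That list no longer stood apart with no floor, with the median over probe sets, or without _x_at and _s_at probe sets, where the percentile was as low as 90.3. HRAS was 1.65-fold higher, under the 2-fold threshold.

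**Figure D2:**
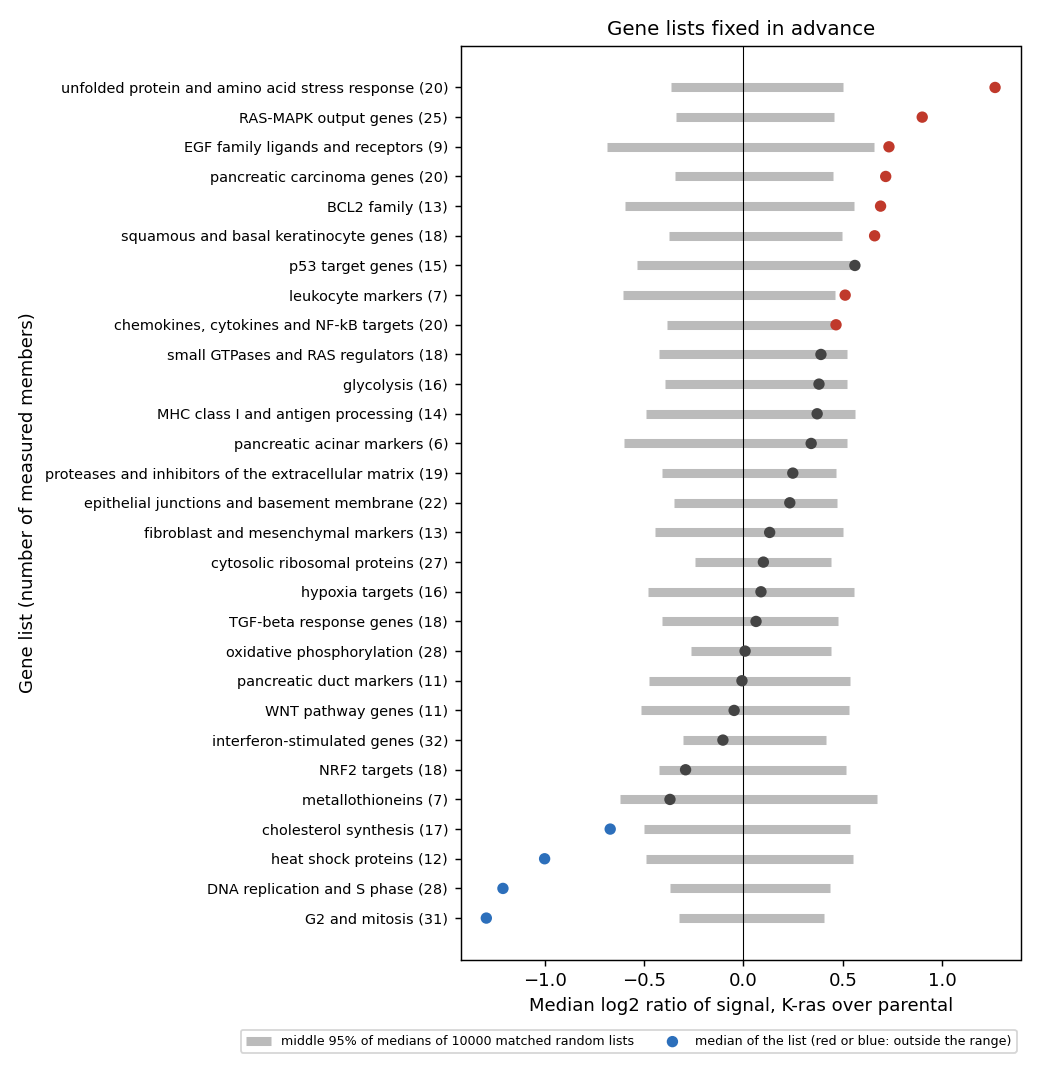
Median log2 ratio of signal, K-ras over parental (x axis), for the 29 gene lists with at least 5 measured members (y axis, number of measured members in brackets), with grey bars for the middle 95% of medians of 10000 random lists matched on signal. The stress list (1.27) and the RAS-MAPK list (0.90) lie furthest to the right of their bars, and the mitosis list (-1.29) and the replication list (-1.21) furthest to the left.

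Transcripts known from pancreatic carcinoma and from squamous epithelium were shifted to the higher side. In the pancreatic carcinoma list (median log2 ratio 0.72, percentile 99.96) 6 of 20 measured members were at least 2-fold higher and none lower. They were SLPI, S100P, the metalloproteinase inhibitor TIMP1 (2.64-fold), GPRC5A (log2 ratio 1.32), LCN2 (log2 ratio 1.23) and CEACAM5 (at least, 1.01). In the keratinocyte list (0.66, percentile 99.8) 5 of 18 were at least 2-fold higher, namely KRT16, PI3, SPRR1B, SPRR1A (4.12-fold, uncertain) and SPRR3 (log2 ratio 1.46), while the basal keratins KRT5 and KRT14 had log2 ratios of 0.66 and 0.70. In the BCL2 family (0.69, percentile 99.4, 13 measured) the apoptosis promoter PMAIP1 was 2.74-fold and the apoptosis inhibitor BCL2L1 2.14-fold higher, and no member was at least 2-fold lower. The BCL2 list no longer stood apart with the median over probe sets or without _x_at and _s_at probe sets (percentile as low as 92.5), nor did the keratinocyte list under quantile normalization or a floor at the 30th percentile (as low as 97.1). The cytokine and NF-kB list (0.47, percentile 97.97) had 6 of 20 at least 2-fold higher, among them IL1B (5.04-fold), the prostaglandin synthase PTGS2 (5.04-fold), NFKB2 (3.86-fold) and CXCL3 (at least 3.33-fold), and IL1A lower with a log2 ratio of -1.04. The neutrophil chemokine CXCL8 had a log2 ratio of -0.15 on an uncertain probe set. The cytokine list stood apart under 5 of the 11 alternative settings. After removal of a trend with gene span and genomic neighbourhood, a step chosen after the data were seen, the percentiles of these 4 lists were 91.9, 91.1, 94.7 and 96.6, inside the limits.

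Transcripts of the cell cycle were lower in the K-ras line. In the DNA replication list, 17 of 28 measured members were at least 2-fold lower and none higher, with a median log2 ratio of -1.21, below all matched random lists. The helicase subunit MCM6 was 7.94-fold lower, thymidylate synthase TYMS 5.55-fold, the ribonucleotide reductase subunit RRM1 4.89-fold and the polymerase clamp PCNA 4.76-fold, while E2F1 and CDT1 had log2 ratios of 0.18 and 0.01. In the mitosis list, 20 of 31 were at least 2-fold lower and none higher, with a median of -1.29, again below all random lists. The cyclin-dependent kinase CDK1 was 8.91-fold lower, with log2 ratios of -3.38 and -3.15 in 2 probe sets. TOP2A, DLGAP5 and NEK2 were at least 7.67-fold, 6.99-fold and 5.75-fold lower, and UBE2C and CDC25B had log2 ratios of 0.26 and 0.62. Both lists stood apart under each of the 11 alternative settings. CDKN1A, the cyclin-dependent kinase inhibitor p21, was 4.48-fold higher. It belongs to the p53 target list, which had 5 of 15 members at least 2-fold higher (with PHLDA3 at 3.73-fold and GADD45A at 3.01-fold) and 2 lower, PLK2 (2.95-fold) and FAS (log2 ratio -1.17). That list's median of 0.56 lay at percentile 97.4, just inside the limits, and between 82.5 and 99.8 under the alternative settings, outside them in 3 of 11.

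Cytosolic chaperones and sterol synthesis genes were lower too. Of 12 measured heat shock genes 6 were at least 2-fold lower and none higher, with a median log2 ratio of -1.001 and a percentile of 0.03. After HSP90AA1 these were HSPH1 (at least 8.57-fold), DNAJA1 (7.81-fold), the mitochondrial pair HSPE1 (2.52-fold) and HSPD1 (log2 ratio -1.08), and HSP90AB1 (-1.23). Of 17 cholesterol synthesis genes 6 were lower and 1 higher (median -0.67, percentile 0.70). HMGCS1, which makes the precursor of mevalonate, was at least 10.6-fold lower, MSMO1 6.43-fold, IDI1 4.86-fold on an uncertain probe set and squalene epoxidase SQLE 3.50-fold. The transcription factor SREBF2, which drives this pathway, had a log2 ratio of 1.58, and 0.76 in a second probe set. Without _x_at and _s_at probe sets the percentile of the cholesterol list was 6.46, inside the limits.

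**Figure D3:**
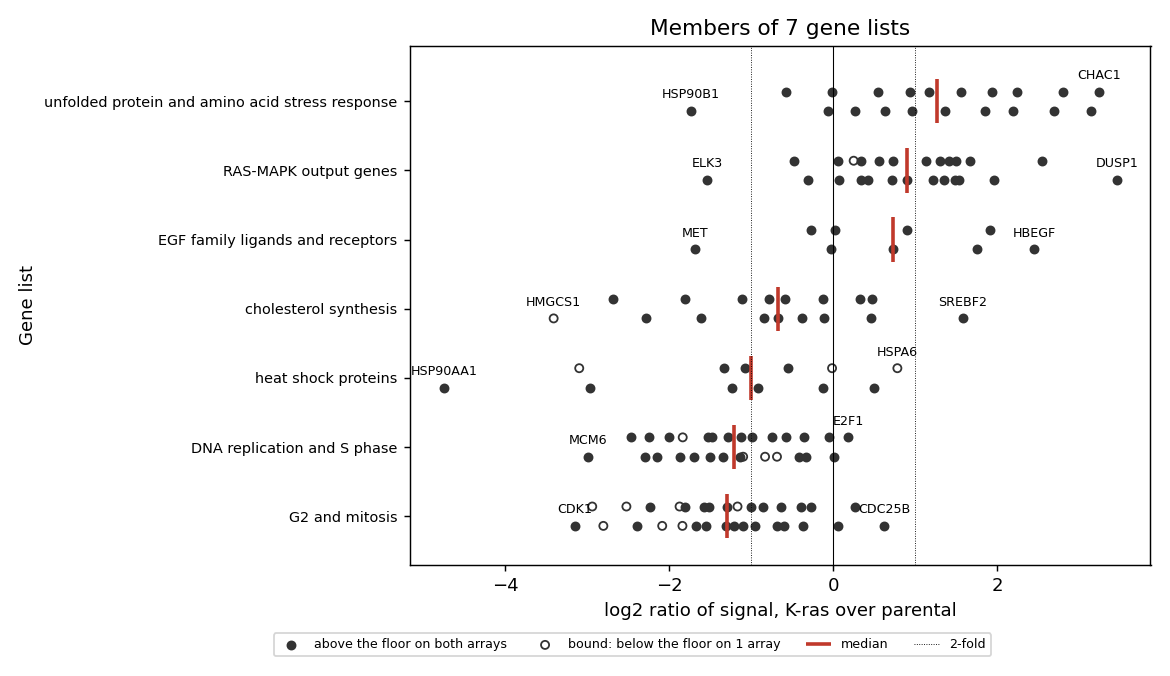
log2 ratio of signal, K-ras over parental (x axis), of each measured member of the gene lists named on the y axis, with filled points for genes above the floor on both arrays, open points for bounds, red lines for list medians and dotted lines at 2-fold. No member of the replication or mitosis list reaches 2-fold higher, and HSP90AA1 (-4.75) is the lowest point shown.

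Junction genes went both ways, and some duct markers were lower. Among 22 junction and basement membrane genes, 4 were at least 2-fold higher and 6 lower (median log2 ratio 0.23, percentile 73.5). The hemidesmosome gene ITGB4 was 3.40-fold higher, with LAMB3, ITGA3 and the desmosome gene PKP3 at log2 ratios of 1.38, 1.24 and 1.08. DSG2, TJP1 (3.21-fold, with another probe set at a log2 ratio of -0.44) and DSP (2.98-fold) were lower. PKP1, CLDN1, CLDN7 and JUP had log2 ratios of 0.92, 0.93, 0.78 and 0.47, under 2-fold. The cadherin CDH1 had a log2 ratio of -0.03. Of 18 duct markers 11 were measured, and CFTR, SPP1, PROM1, CLDN4, ONECUT2 and TFF2 were below the floor on both arrays. Of the 11, 4 were lower and none higher. The lower ones were carbonic anhydrase CA2 (at least 5.69-fold), the duct keratin KRT19 (2.74-fold), EPCAM (2.08-fold) and SOX9 (2.05-fold, with a second probe set at 0.04). The keratins KRT7, KRT18 and KRT8 had log2 ratios of -0.32, 0.38 and 0.88, the last 2 on uncertain probe sets. The median of the 11 duct markers was -0.01 (percentile 29.6), too near 0 to have a direction. With the floor at the 70th percentile the duct list stood apart, at percentile 0.08. Among 19 matrix proteases and inhibitors, 7 were higher and 2 lower (median 0.25, percentile 78.4), with the collagenase MMP1 4.33-fold and ADAM8 4.18-fold higher and ADAM9 6.38-fold and ADAMTS1 5.32-fold lower.

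The lists of interferon, signalling, stress defence and metabolism genes described next did not stand apart. In the interferon list (median log2 ratio -0.10, percentile 15.3) 4 of 32 genes were higher, with OASL at 4.90-fold, ISG20 at 3.54-fold and IRF7 at 3.17-fold, and 6 were lower, with IFI16 at 4.05-fold on an uncertain probe set. MHC class I genes had a median of 0.37 (percentile 86.7), with 2 of 14 higher, HLA-E (2.94-fold) and HLA-B (2.30-fold), both on uncertain probe sets of a multigene family. Hypoxia targets had a median of 0.09 (percentile 49.3), with 3 of 16 higher (NDRG1, STC2 and the growth factor VEGFA at 5.22-fold) and 3 lower, among them ANGPTL4 at 2.87-fold. In the TGF-beta list (0.06, percentile 44.3) BMP2 (at least 4.68-fold) and INHBA (3.12-fold) were higher and CCN2 was 2.73-fold lower. In the WNT list (-0.05, percentile 27.2) DKK1 (2.91-fold), SFRP1 (2.67-fold) and CTNNB1 (2.07-fold) were lower and WNT7B at least 2.27-fold higher. Another SFRP1 probe set gave a log2 ratio of only -0.35. Among small GTPases and RAS regulators (0.39, percentile 89.7) RHOB (2.54-fold), RRAS (2.52-fold), RASSF1 (at least 2.28-fold) and RIN1 (log2 ratio 1.01) were higher and SOS1 (at least 2.18-fold, with another probe set at -0.27) and RND3 (-1.07) lower. NRF2 targets had a median of -0.29 (percentile 6.40), with 5 of 18 lower and none higher. AKR1C3 was at least 3.20-fold lower, GCLM 2.66-fold and TXNRD1 2.48-fold, and SLC7A11 (2.35-fold lower) had another probe set with a log2 ratio of 1.39. Metallothioneins had a median of -0.37 (percentile 8.09), with MT1F 2.14-fold lower on an uncertain probe set. In glycolysis (0.38, percentile 89.0) 1 of 16 members passed 2-fold, PFKM at 2.21-fold lower. Oxidative phosphorylation (0.01, percentile 29.98) had 3 of 28 higher and 3 lower, led by NDUFS1 at 3.24-fold lower and UQCRC1 at 2.45-fold higher. None of 27 ribosomal protein genes passed 2-fold (0.10, percentile 42.3). The medians of the interferon, hypoxia, TGF-beta, WNT, oxidative phosphorylation and ribosomal lists lay so near 0 that their sign depends on the scaling and gives no direction.

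Many markers of fibroblasts, leukocytes, endothelium, acinar and endocrine cells were below the floor on both arrays. Of 28 fibroblast and mesenchymal markers 13 were measured and none was at least 2-fold higher (median log2 ratio 0.13, percentile 56.3). FN1 (2.60-fold, uncertain) and SNAI2 (2.37-fold) were lower. The highest parental signals in that list were 1989 for FN1, 952 for SPARC, 945 for SNAI2 and 590 for VIM. Of 21 leukocyte markers 7 were measured, none passing 2-fold, and the highest signal was 139, for CD53 on the K-ras array. Their median of 0.51 stood apart at percentile 98.4, but not with no floor or with the floor as a pseudocount, where it was as low as 79.3, nor after removal of the trend with gene span and neighbourhood (90.5). Of 20 acinar markers 6 were measured (median 0.34, percentile 87.9). One was at least 4.17-fold higher, PRSS2, on an uncertain probe set of the trypsinogen family, with another at a log2 ratio of 1.24. MHC class II, endothelial and endocrine markers had 3, 3 and 2 measured members, too few to rank, and none passed 2-fold. Control probe sets along GAPDH and ACTB are meant to report on the length of the RNA, but their signals were near the top of the scale. The log2 ratio of the 5' part of GAPDH was 0.28 and that of its 3' part 0.40, and for ACTB the values were 0.30 and 0.08.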

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

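Probe sets that the annotation pairs with several genes or with none were left out of the report's comparison, and they also carried differences against the parental array, which serves as the control. Controls and probe sets naming XIST or a Y-linked gene aside, there were 3129 of them, and 1394 were above the floor on at least 1 array. Among them 106 (7.60%) were at least 2-fold higher and 147 (10.5%) at least 2-fold lower in the K-ras line. Their source genes were not examined.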

How the results depend on the processing

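The removal of the trend with gene span and neighbourhood was the one alternative chosen after the data were seen. The counts of genes depended mainly on the floor, the threshold and the choice of probe sets. Against 767 genes higher and 1108 lower, a floor at the 30th percentile gave 1362 higher, a floor at the 70th percentile 451 higher and 632 lower, and no floor 2419 higher and 1796 lower. The floor as a pseudocount gave 469 higher, leaving out _x_at and _s_at probe sets 460 higher and 721 lower, and a 3-fold threshold 185 higher and 479 lower. By construction a lower floor tests more genes and fewer probe sets fewer. The other counts stayed within 1.5 times the main ones, including 693 higher and 885 lower after removal of that trend. After it 11 lists stood apart, without the BCL2, cytokine, leukocyte, carcinoma and keratinocyte lists and with the metallothionein, p53, acinar and protease lists. The number of lists standing apart was 12 and lay between 10 and 12 under the other alternatives. For the 29 list medians none of 313 values under the alternatives reversed a list that stood apart, and 33 moved by more than the spread of random lists. For 151 named genes none of 1591 values reversed a gene at 2-fold or more, and 139 moved by more than the spread between probe sets. Lists inside the limits that left them under some setting were the p53 targets (as high as 99.8), proteases (99.96), MHC class I (98.7), NRF2 targets (2.12), duct markers (0.08) and, after removal of the trend, acinar markers (97.8) and metallothioneins (1.36). The cause was not tested. No paired analysis was possible because each group holds 1 array, and for the same reason no replicate could be left out. Signals near the floor limit the data, since 1695 of 7690 genes have bounds and 4249 were below the floor on both arrays.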

Other observations

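The lists in this part were chosen after the table of genes had been seen, so their percentiles describe lists picked with the values known. The tests of signal distributions, tRNA synthetases, culture state, RNA ends, subunits and base composition were also chosen after the result was seen.

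Several multi-subunit machines of the cell were lower in part. Of 18 nuclear transport genes 13 were at least 2-fold lower and none higher (median log2 ratio -1.46, below all matched random lists), led by the export receptor XPO1 (-2.89) and the import receptor KPNA3 (-2.60, with another probe set at 0.01), while KPNA4 was at -0.04. Of 7 measured subunits of the chaperonin CCT, which folds actin and tubulin, 5 were lower and none higher (median -1.33, percentile 0.01), led by CCT8 (-1.98). Of 28 proteasome genes 11 were lower and none higher (median -0.73, percentile 0.01), with PSMC6 at or below -3.26 and PSMD2 at 0.62. The COP9 signalosome ran from COPS2 (at or below -3.68) and COPS4 (-2.75) to COPS7A (0.56), with 4 of 8 lower (median -0.77, percentile 2.39). Spliceosome genes had a median of -0.29 (percentile 2.79, inside the limits), with 3 of 24 lower and 1 higher. Over all measured genes 14.4% were lower, so the spliceosome did not stand out.

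The stress list was divided after its values were seen, so its parts restate the result for the list. The amino acid and ATF4 part had a median of 2.20 over 11 genes with 8 at least 2-fold higher, and its endoplasmic reticulum chaperone part a median of 0.55 over 9 genes (percentile 93.8) with 3 higher and 1 lower. Of 10 amino acid transporters 4 were at least 2-fold higher and 1 lower (median 0.81, percentile 99.86), with SLC1A4 3.99-fold higher on an uncertain probe set, SLC3A2 at 1.60, SLC38A1 at -0.66 and SLC7A11 at -1.23, the last with another probe set at 1.39.

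For the higher level of amino acid stress genes, a different shape of the signal distributions was argued against by the median of the list. That median was 1.27, and it was 1.28 under quantile and 1.24 under loess normalization. The percentile, 100 in both, adds little, since random lists matched on signal shift with the list. The trend with gene span and genomic neighbourhood was argued against as the whole cause, since the median was 1.17 after its removal (percentile 100). Span and neighbours accounted for 15.9% of the variance of the log2 ratio, so this removal does not test RNA quality or base composition. An ATF4-type response was tested on tRNA synthetases, where those known to respond to ATF4 had a median of 0.80 over 11 genes (percentile 99.62), 3 of them at least 2-fold higher and 1 lower, with CARS1 at 1.59 and EPRS1 at -2.27, and the others a median of -0.53 over 5 genes (percentile 12.6). As a hypothesis, the K-ras culture may have been under amino acid or related stress at harvest. Whether that came from the oncogene or from the state of the culture cannot be told apart with 1 array per line.

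As a hypothesis, the lower level of replication and mitosis genes may reflect fewer dividing cells in the K-ras sample, but the share of dividing cells was not measured and this was not tested. A different shape of the 2 signal distributions and the trend with gene span and genomic neighbourhood were both argued against as the whole cause. The median of the replication list, -1.21, was -1.19 under quantile and -1.23 under loess normalization and -1.29 after removal of the trend. That of the mitosis list, -1.29, was -1.23, -1.34 and -1.15, and all these values lay at percentile 0. Under the 2 normalizations the percentile adds little, since random lists matched on signal shift with the list. Span and neighbours accounted for 15.9% of the variance of the log2 ratio, so removing their trend does not test RNA quality or base composition. For these 2 lists, effects of RNA quality and of base composition stay open and were not tested. The same holds for effects of the oncogene, of the clone or pool, and of culture density.

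The log2 ratio was related to where a gene lies and how long it is. The 1538 genes of shortest genomic span (up to 9717 bp) had a median log2 ratio of 0.34 and the 1538 of longest span (from 88151 bp) -0.14, with a Spearman rho of -0.24 over 7688 genes, which are not independent replicates. A gene's ratio correlated with the median of its 20 nearest measured neighbours at rho = 0.39, against at most 0.04 over 100 shuffled gene orders. Chromosomes 19 and 22 had the highest medians (0.52 and 0.44) and chromosomes 4 and 18 the lowest (-0.37 and -0.24).

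For this trend, gain or loss of whole chromosomes was argued against as the whole cause of the relation to span by a median rho of -0.18 within chromosomes (below 0 in 22 of 23). The relation to neighbours was not tested in this way, and gain or loss of parts of chromosomes stays open. Within lists the ratio also followed the value given by span and neighbours. Its rho was 0.67 within the proteasome and 0.68 within the oxidative phosphorylation list (28 genes each), against 0.41 over all genes. Within the COP9 signalosome it was 0.81 (8 genes). The trend was fitted to these same ratios, so the values cannot tell a property of the transcripts from other sources. Degraded RNA in the K-ras sample stays open, since the lower of the 2 log2 ratios of 5' over 3' signal of GAPDH and ACTB was -0.12 but all their signals were at least 59.6% of the highest of their array, where changes may be compressed. Base composition, known to vary along chromosomes, is a candidate explanation that could act through labelling or through RNA turnover in the cells, and it cannot be told apart from other causes because 0 transcript or probe sequences were used.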
